A study of Mus musculus with 6 samples.

How the data were processed

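RNA from reporter-positive B lineage cells, sorted from the small intestinal lamina propria and from the bone marrow of young mice, was measured on 6 whole-transcript arrays with a biotin label, 3 per tissue. Per the labels, the mice were 17 to 25 days old, 8 to 12 mice were used in each experiment, and the 3 replicates of a tissue were independent. Per the labels' protocols, RNA was extracted with Trizol and 4.5 to 47 ng were amplified with a whole-transcriptome kit for small amounts before labelling. Which sample had how much RNA is not given in the sources used here. The authors deposited log2 values made by RMA in Affymetrix Expression Console 1.3.0.187, per the submitters' processing notes. RMA in general subtracts background, equalises the distributions of arrays and summarises probes. The settings used are not given in the sources used here. Where RMA forces alike distributions, a loss of many transcripts in 1 array also moves the other values of that array.

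The values were used as deposited, with no further scaling or filter. The file held 35556 probe sets. The platform's gene table gave 1 gene symbol for 21789 of them and several for 1621, and did not list 12146, which are unnamed here. Of those with 1 symbol, 21698 had their Entrez identifier in the RefSeq table of GRCm38.p6, through which 0 symbols changed. The 13767 probe sets without exactly 1 symbol entered no comparison of genes or lists, and were compared between the tissues only as probe sets. A gene with several probe sets was represented by the 1 with the highest mean over all arrays. This left 19938 genes, of which 999 had several probe sets, and in 255 of these the probe sets differed between the tissues in opposite directions. No coordinates were used here.

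Lamina propria was compared with bone marrow in limma 3.58.1 under R 4.3.3 (lmFit and eBayes, no trend, not robust, no block, two-sided), with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05. Differences are lamina propria minus bone marrow on the log2 scale, with 95% intervals from the moderated variances. Pools of animals were the replicates, so limma p-values measure the spread between pools. An exact test of 3 against 3 cannot give a two-sided p below 0.1, and none was used for single genes. The 18 gene lists and 9 marker lists were tested with camera at its preset correlation of 0.01, with adjustment over the 27 lists. Each list median was also set against 10000 random lists of the same size, matched on mean level. Both set list members against other genes, so their p-values do not measure the spread between pools. Of the listed genes, those with no probe set of 1 symbol were not analysed here.

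The groups, tests, gene lists, alternatives and the rule for naming genes were chosen before the data were examined. The rule took the 10 genes with the largest difference in each direction among those past the threshold with no overlap, of which there were none. It took up to 4 members of each list past the threshold or, where none passed, the 2 with the highest mean level, and a fixed set of 16 genes of B cell development. The other members named were picked after their values were seen, to show how a list was made up: Xrcc4, Prkdc, Atm, Hmgb1, Nhej1, Atf3, Hspa1a, Jun, Cd74 and Cflar.

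The alternatives were the pool number as a block, a filter on dim genes, 2 further scalings, an intensity trend with robust variances, array weights, other rules for several probe sets, a stricter threshold of 0.01 for genes, camera with an estimated correlation, fry, matched random lists and leaving out each array. Leaving out lamina propria pools 1 and 2 together, and the threshold of 0.01 for lists, were added after seeing the data. The tests were tested on simulated data with 19938 genes, 200 of them changed, for the comparison of 3 lamina propria with 3 bone marrow arrays. With the spread of all 6 arrays, 0% of genes changed by 1 log2 unit were recovered, 86.7% of those changed by 2 and 96.8% of those changed by 3. With the spread of the bone marrow arrays these shares were 74.8%, 97.2% and 99.4%. Simulated genes varied independently, with the same spread in both tissues and without the shift that lamina propria pools 1 and 2 share. These shares may thus be too high for the real arrays, where Rag2, at -2.35, did not pass. Figures were drawn with matplotlib 3.10.9.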

Results

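Gene expression was compared between B lineage cells that still carried the recombination reporter in 2 mouse tissues, the lamina propria of the small intestine (the connective tissue layer under the gut epithelium) and the bone marrow, the main site of B cell formation. The mice carried a green fluorescent reporter of Rag2, a gene needed to assemble antigen receptor genes, so fluorescence marks cells that recombine these genes or did so recently. The animals were 17 to 25 days old, 8 to 12 mice went into each experiment, and each tissue gave 3 independent pools of sorted cells, each hybridised to 1 array. The labels state the comparison of the tissues' expression profiles as the purpose. The values were log2 RMA values, with medians over all probe sets between 5.34 and 5.48 in the 6 arrays. They covered 19938 genes, and the number of arrays limits the precision.

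Most measured genes of V(D)J recombination lay lower in the lamina propria. Of 12, 9 had a negative difference, 6 of them with no overlap, and 3 a positive one. Rag2, which with Rag1 encodes the enzyme that cuts at recombination signals, averaged 5.83 ± 0.21 (SD, n = 3) in the lamina propria and 8.18 ± 0.38 (SD, n = 3) in the bone marrow, a log2 difference of -2.35 (95% interval -2.95 to -1.75) or 5.11-fold. Rag1 averaged 9.97 ± 0.44 against 11.02 ± 0.12 (SD, n = 3 each), a difference of -1.05 (95% interval -1.66 to -0.44). Xrcc4, a partner of DNA ligase IV in end joining, differed by -2.62 (95% interval -3.42 to -1.82), and Dntt, which adds untemplated nucleotides at the joints, by -0.51 (95% interval -0.97 to -0.06). For these 4 genes every lamina propria pool lay below every bone marrow pool. Each missed the threshold over all genes, with limma adjusted p of 0.155 for Rag2 and Xrcc4, 0.307 for Rag1 and 0.356 for Dntt. With an intensity trend and robust variances, Rag2 (adjusted p = 0.0456) and Xrcc4 (adjusted p = 0.0362) passed. Both also passed with the pool number as a block (limma adjusted p = 0.0476 each), though the numbers are not known to pair the samples.

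As a group, the 12 measured genes of the V(D)J recombination machinery fell in the lamina propria (camera, preset correlation, adjusted p = 8.14e-06 over 27 lists), with a median difference of -1.05. The call was lost with an estimated correlation (adjusted p = 0.489 with an estimated correlation). The list's median stood at percentile 0.02 of random lists matched on mean level, which draw genes independently. None of the 12 passed over all genes, 6 were lower adjusted over the list alone, and 6 had no overlap between the tissues, among them Prkdc and Atm, kinases of the response to DNA breaks, at -1.04 and -1.39. The 3 members with a positive difference were Hmgb1, Hmgb2 and Nhej1, at 0.29, 0.05 and 0.21. Hmgb2, an abundant chromatin protein that helps the recombinase bend DNA, averaged 11.21 ± 0.04 and 11.15 ± 0.25 (SD, n = 3 each). In pool 3 alone, the lamina propria array closest to the bone marrow arrays, the list's median difference was -0.52.

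**Figure D1:**
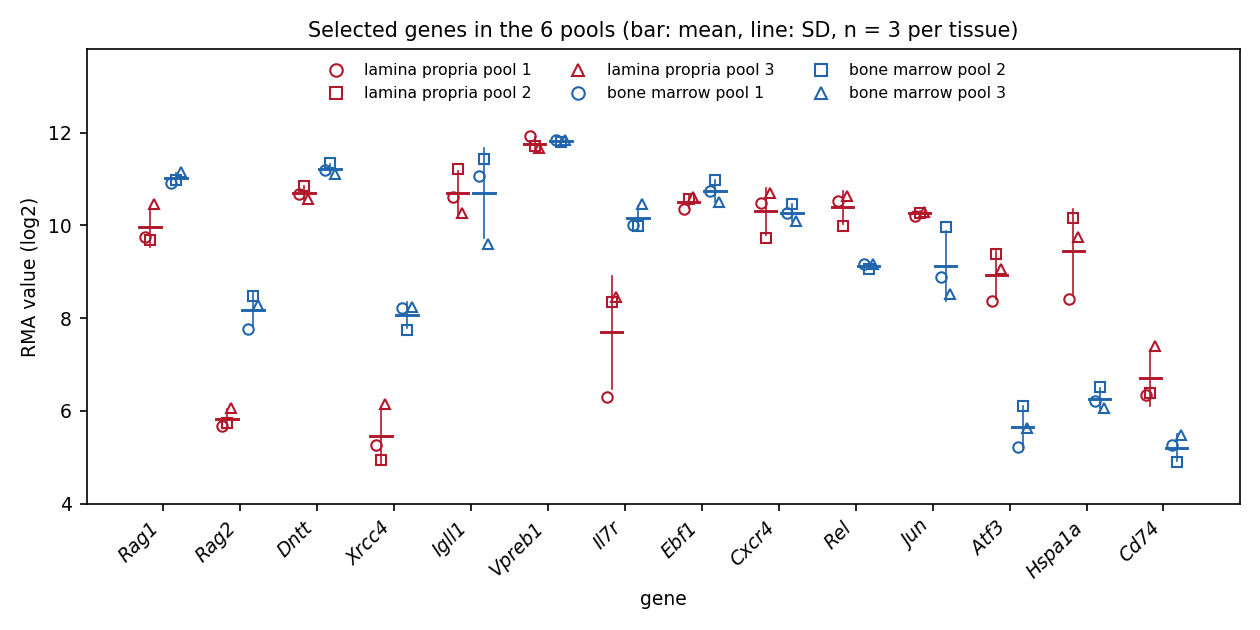
RMA value (log2) of 14 genes in the 3 lamina propria pools (red) and the 3 bone marrow pools (blue), with the mean as a bar and the SD as a line. Rag1, Rag2, Dntt, Xrcc4 and Il7r lie lower and Rel, Jun, Atf3, Hspa1a and Cd74 higher in every lamina propria pool, while Igll1, Vpreb1, Ebf1 and Cxcr4 overlap.

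Genes of the pro-B and pre-B stages, the steps at which the receptor chains are assembled, gave mixed differences. Il7r, the receptor for the growth factor of early B cells, differed by -2.46 (95% interval -3.77 to -1.15, limma adjusted p = 0.285), with lamina propria pools at 6.29, 8.35 and 8.45 against a marrow mean of 10.16 ± 0.26 (SD, n = 3). The surrogate light chain genes Igll1 and Vpreb1 differed by 0.00 (95% interval -1.16 to 1.16) and -0.06 (95% interval -0.50 to 0.39). Cd24a, at 11.49 ± 0.30 and 11.66 ± 0.17 (SD, n = 3 each), differed by -0.17 and Kit, a receptor of early progenitors, by 0.02 (95% interval -1.11 to 1.15). Of 18 measured members 14 had a negative difference, 2 were lower adjusted over the list alone and none passed over all genes. The list fell by camera (adjusted p = 0.00315, median -0.22), but not with an estimated correlation (adjusted p = 0.489 with an estimated correlation), and its median stood at percentile 40.8 of 10000 random lists matched on mean level. Its median was -0.604 without lamina propria pool 3, and -0.147 with no call (adjusted p = 0.097) in pool 3 alone.

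Among genes of B cell identity, Ebf1, Pax5 and Cd79a differed by -0.22 (95% interval -0.72 to 0.27), -0.62 (95% interval -2.12 to 0.87) and 0.04 (95% interval -1.10 to 1.18), and the adaptor Blnk by -0.23. None of the 19 measured members passed over all genes or adjusted over the list alone. The list fell by camera (adjusted p = 0.0109, median -0.31), but not with an estimated correlation (adjusted p = 0.605 with an estimated correlation). Its median stood at percentile 51.92 of random lists matched on mean level, which themselves had a median of -0.325. Against genes of the same level the list was thus not lower, and its fall by camera does not set it apart from them. The list had a median of 0.11 in pool 3 alone. It also missed the threshold without lamina propria pool 2 (adjusted p = 0.106, median -0.13) or marrow pool 1 (adjusted p = 0.121, median -0.23). Ighm, the constant region of IgM, differed by -0.33 (95% interval -1.27 to 0.60) and Igha, that of IgA, by -1.31 (95% interval -2.67 to 0.04), and the list of immunoglobulin constant regions, with 3 measured members, had a median of -0.33 (adjusted p = 0.531). That median was 0.58 in pool 3 alone, with Ighm 0.58 above and Igha 0.14 below the marrow mean, and ran from -0.788 to -0.018 when 1 array was left out, the former without lamina propria pool 3. The gut-homing receptor Ccr9 and the marrow-retention receptor Cxcr4 differed by 0.15 (95% interval -0.43 to 0.73) and 0.03 (95% interval -0.65 to 0.71). Ccr9 averaged 4.48 in the lamina propria and 4.33 in the bone marrow, below the median of every array, so its small difference says little. Cxcr4 averaged 10.31 and 10.27. The integrin chain Itga4 differed by -0.42, and the 13 homing and chemokine receptor genes had a median of 0.15 (adjusted p = 0.944), which was 0.031 without pool 3 and -0.035 in pool 3 alone.

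Immediate early and stress genes, which respond within minutes to stimulation or handling, were higher in the lamina propria. Atf3, a stress-induced transcription factor, averaged 8.93 against 5.65, a difference of 3.28 (95% interval 2.48 to 4.09), and Hspa1a, an inducible heat shock protein, 9.44 against 6.26, a difference of 3.18 (95% interval 2.15 to 4.203), each with n = 3 per tissue and limma adjusted p = 0.155. With an intensity trend and robust variances Atf3 passed (adjusted p = 0.0362) and Hspa1a did not (adjusted p = 0.0642). With the pool number as a block both passed (limma adjusted p = 0.0476 each), though the numbers are not known to pair the samples. The heat shock genes Hsp90aa1 and Hspa8 differed by 0.65 and 0.28. Of 19 measured members 18 had a positive difference, 8 had no overlap, 4 were higher adjusted over the list alone and none passed over all genes. The list rose by camera (adjusted p = 5.55e-05, median 0.78), but not with an estimated correlation (adjusted p = 0.605 with an estimated correlation). Bone marrow pool 2 also stood high for this list, with a median 0.62 above the other marrow pools. Without lamina propria pool 3 the list no longer passed (adjusted p = 0.113, median 0.68).

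Among NF-kB target genes, Rel, itself a subunit of the factor, was higher in each lamina propria pool, by 1.26 (95% interval 0.71 to 1.81, limma adjusted p = 0.226), while the activation marker Cd69 differed by 2.31 with overlap between the tissues. The 12 measured members had a median of 0.47, with 11 positive (camera adjusted p = 0.158), and 1 was higher and 1 lower adjusted over the list alone. That median stood at percentile 99.98 of random lists matched on mean level, which draw genes independently. Cflar, an inhibitor of caspase activation, was the member with a negative difference, at -3.52. The 8 MHC class II presentation genes had a median of 0.45 (adjusted p = 0.491) with 1 higher adjusted over the list alone. H2-Ab1 differed by 0.47 and H2-Ob by -1.19, both with overlap. Without lamina propria pool 3 the median was 0.086 (adjusted p = 0.958), and in pool 3 alone the MHC class II and NF-kB target lists passed with medians of 0.79 and 0.70. The 14 glycolysis and hypoxia genes had a median of 0.31 (adjusted p = 0.771), with Pkm at 0.73 and Pgk1 at -0.48.

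Cell cycle genes were lower as a list (27 members, median -0.33, camera adjusted p = 0.00743), and this call was lost with an estimated correlation (adjusted p = 0.518 with an estimated correlation). The list's median stood at percentile 3.09 of random lists matched on mean level. Pcna, the sliding clamp of DNA replication, averaged 10.69 ± 0.32 against 11.26 ± 0.07 (SD, n = 3 each), a difference of -0.57. The helicase subunit Mcm6 differed by -0.82 with overlap between the tissues, and lay 0.18 above the marrow mean in pool 3. Of the 27 members, 6 lay above all 3 marrow pools in pool 3, 15 inside their range and 6 below. No member passed over all genes or adjusted over the list alone. In pool 3 alone the list's median was -0.09, against -0.43 and -0.48 in pools 1 and 2, and without marrow pool 3 the call was lost (adjusted p = 0.0802, median -0.10). The 10 p53 target genes had a median of 0.20 and a mean of -0.12 (adjusted p = 0.944), with Trp53inp1 at -1.23 and Ccng1 at -1.56, and a median of 0.367 without pool 3 and 0.023 in pool 3 alone.

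Lists of later B cell stages and of responses to microbes did not pass. Medians were 0.15 for mature B genes (Tnfrsf13c at 0.31, S1pr1 at 0.45, adjusted p = 0.944), 0.21 for plasma cell genes (Sec11c at -0.60, Irf4 at 0.08, adjusted p = 0.65) and 0.34 for germinal centre and class switching genes (Tnfrsf13b at 0.21, S1pr2 at 0.26, adjusted p = 0.34). Fetal-type and B-1 genes had a median of 0.40 (Arid3a at -0.06, Zbtb32 at 0.43, adjusted p = 0.531), with 1 member lower adjusted over the list alone. The interferon response list, with Ifit2 at 0.00 and Oasl1 at 0.62, had a median of 0.00, a mean of -0.12 and a camera direction of lower (adjusted p = 0.233). The microbial sensing list, with Tlr2 at -0.10 and Nod2 at 0.49, had a median of -0.08 (adjusted p = 0.158). The 55 ribosomal protein genes, with Rps6 at -0.01 and Rps20 at -0.07, had a median of 0.11 and a mean of 0.07. By contrast camera, which compares their test statistics with those of other genes, gave the direction lower (adjusted p = 0.531). Their direction was not stable. They passed as lower by camera without marrow pool 3 (adjusted p = 0.0264, median -0.119), and as higher among matched random lists (adjusted p = 0.0162). Several of these medians moved with the pools. Without pool 3 they were -0.005 for mature B and 0.653 for fetal-type and B-1 genes, and in pool 3 alone -0.149 for fetal-type and B-1, 0.021 for germinal centre, -0.077 for interferon response and -0.191 for microbial sensing genes.

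Markers of other cell types that a sort from these tissues could hold were tested as 9 further lists. T cell markers rose (14 members, all with a positive difference, median 0.43, camera adjusted p = 0.0178), as did intestinal epithelium markers (22 members, 21 positive, median 0.41, adjusted p = 0.0109). Neither was called with an estimated correlation (adjusted p = 0.665 and 0.605 with an estimated correlation), and no member of either passed over all genes or adjusted over the list alone. Random lists matched on mean level themselves had medians of 0.267 and 0.3, and neither list passed among them (matched random lists, adjusted p = 0.113 each). Positive differences were thus common among genes of these levels. The T cell markers Cd2 and Cd247 differed by 0.27 and 0.08, and the epithelial markers Krt8 and Cdx1 by 0.45 and 0.76. In pool 3 alone the medians were 0.27 and 0.17. Without pool 3 the medians were larger, 0.56 and 0.44, but neither list passed (adjusted p = 0.113 for each). The remaining marker lists did not pass. Their medians were 0.35 for macrophages, monocytes and dendritic cells (Itgam at -0.70, Tyrobp at -0.20, adjusted p = 0.531), 0.41 for mast cells and eosinophils (Siglecf at 0.05, Prg2 at 0.40, adjusted p = 0.233) and 0.29 for erythroid cells (Slc4a1 at 0.29, Gata1 at 0.30, adjusted p = 0.545). They were 0.41 for stroma and endothelium (Pecam1 at -1.14, Col1a1 at 0.55, adjusted p = 0.0996), 0.31 for plasmacytoid dendritic cells (Tcf4 at -0.93, Irf8 at 0.02, adjusted p = 0.531) and 0.28 for natural killer and innate lymphoid cells (Prf1 at 0.33, Tbx21 at 0.46, adjusted p = 0.373). Granulocyte markers had a median of 0.05 and a mean of -0.19 (adjusted p = 0.531). S100a9, a neutrophil protein, averaged 5.50 ± 0.17 in the lamina propria and 7.501 ± 1.53 in the bone marrow (SD, n = 3 each), with marrow pool 2 at 9.26, and Ngp differed by -0.60. In pool 3 alone the medians were -0.44 for granulocyte, -0.032 for mast cell and eosinophil, -0.195 for erythroid, 0.091 for stroma and endothelium, 0.108 for plasmacytoid and -0.035 for natural killer and innate lymphoid cell markers.

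**Figure D2:**
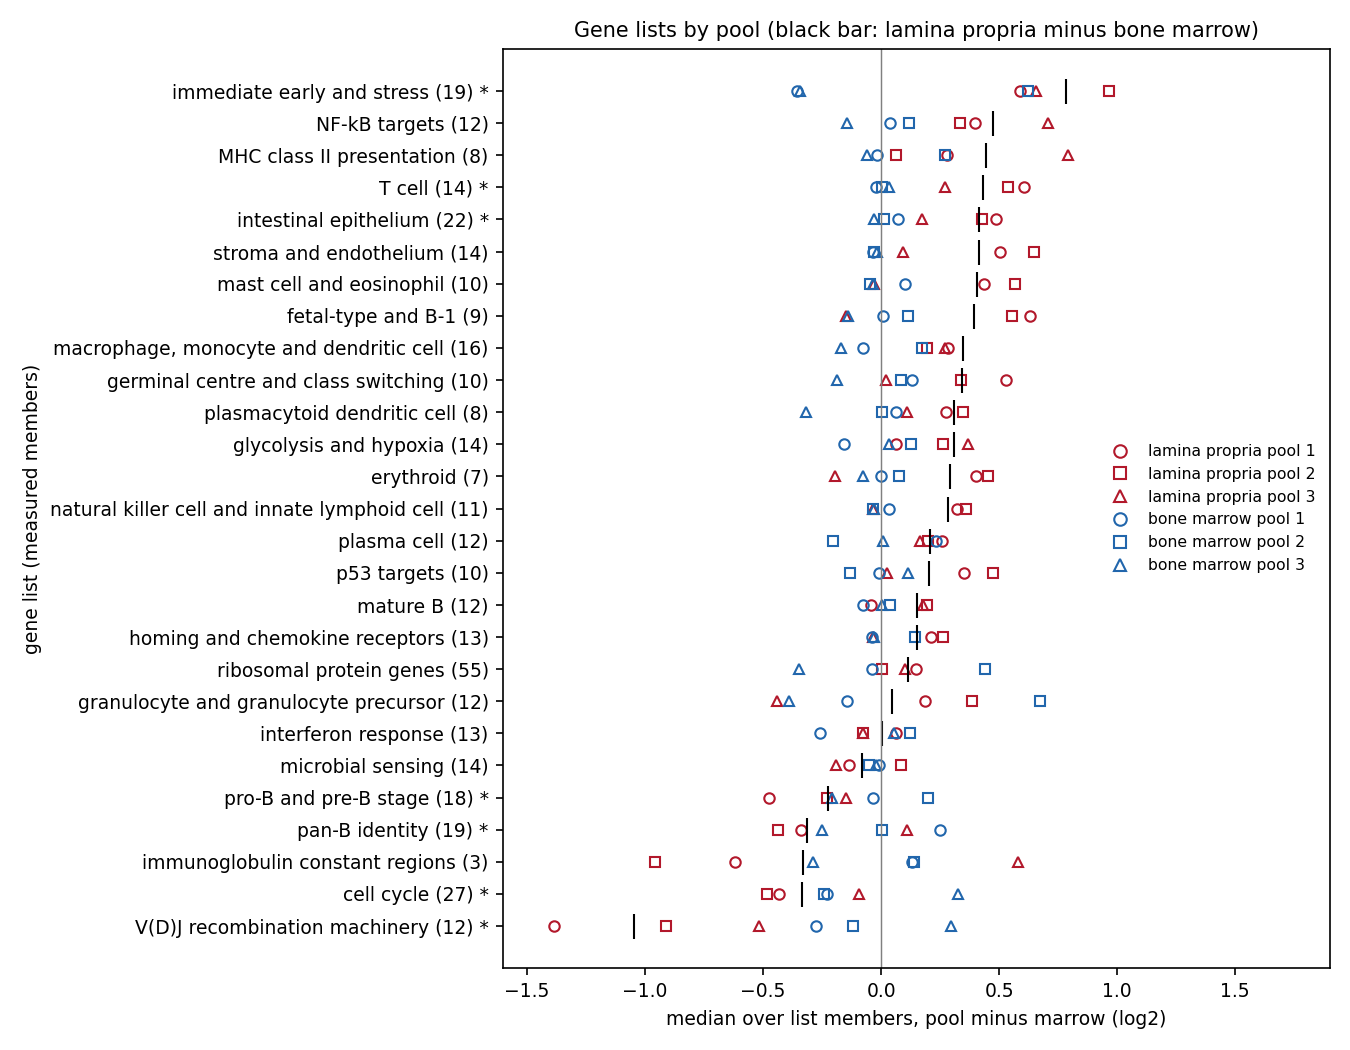
Median over the measured members of each gene list of a pool's value minus the bone marrow mean (minus the mean of the other marrow pools for a marrow pool), in log2 units, for lamina propria (red) and bone marrow (blue) pools. Black bars give the median difference between tissues and a star marks camera adjusted p under 0.05. The V(D)J machinery lies lowest at -1.05 and immediate early and stress genes highest at 0.78.

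Over all 19938 genes, limma called 0 higher and 0 lower at an adjusted p under 0.05, the smallest being 0.155. At an unadjusted p under 0.05 there were 1103 higher and 1625 lower, 2728 in all against 997 by chance. This excess is not specific to the tissues: lamina propria pools 1 and 2 with marrow pool 1, set against the other arrays, gave 2694. The tissues did not overlap for 4410 genes, 22.1% against the 10% that chance gives for 3 against 3, with 2960 higher and 1450 lower. Overlap was not counted for other splits of the arrays. With a difference of at least 1 as well, 67 were higher and 872 lower. The median difference over all genes was 0.22. The count rested on lamina propria pool 3. Without it limma called 4806 genes higher and 2416 lower. In pool 3 the median difference of these genes from the marrow mean was 0.04 and -0.17, against 0.72 and -1.63 over pools 1 and 2. Their median marrow level was 4.87 for those higher and 7.43 for those lower. At these levels most genes of pools 1 and 2 were shifted in the same directions, so the calls do not separate a tissue difference from that shift. With estimated array weights, which gave pool 3 a weight of 0.15 and marrow pool 2 a weight of 2.80, limma called 3368 higher and 2218 lower.

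The lamina propria pools were not alike. Pools 1 and 2 correlated across genes at r = 0.856 with each other and at 0.766 to 0.832 with the other 4 arrays, while pool 3 correlated at 0.954 to 0.966 with the bone marrow arrays, which correlated at 0.957 to 0.980 among themselves. Genes are not independent replicates. The interquartile range of values over all probe sets was 2.00 and 1.94 in pools 1 and 2, 2.47 in pool 3 and 2.41 to 2.46 in the bone marrow. In pools 1 and 2, 981 and 913 genes lay above 8, against 1789 in pool 3 and 1652 to 1903 in the bone marrow. Genes at a bone marrow level of 8 to 9 were lower by medians of 1.38 and 1.55 in pools 1 and 2 and by 0.04 in pool 3. Without pools 1 and 2, limma called 0 genes, and camera called 8 lists higher and 2 lower, the V(D)J machinery (median -0.52, adjusted p = 0.000365) and granulocyte markers (median -0.44, adjusted p = 0.0419). This comparison, chosen after the arrays were seen, assumes that the lone array varies like the marrow arrays.

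**Figure D3:**
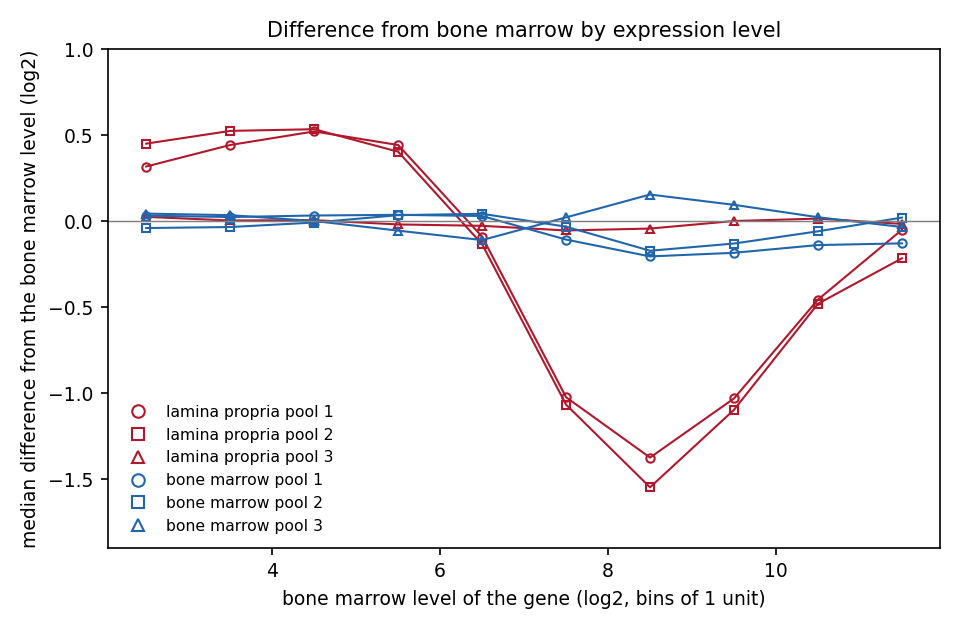
Median difference of each array from the bone marrow level (from the mean of the other marrow pools for a marrow array), in log2 units, over genes binned by that level. Lamina propria pools 1 and 2 lie above 0 for levels under 6 and reach -1.38 and -1.55 at levels of 8 to 9, where pool 3 lies at -0.04.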

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

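A signal appeared among probe sets left out of the comparison of genes, because the gene table names no gene for them. Among these, probe set 10338581 averaged 3.92 ± 0.32 in the lamina propria and 9.41 ± 0.33 in the bone marrow (SD, n = 3 each), a log2 difference of -5.50 with a limma adjusted p of 0.019 over all probe sets of the file, the only one past 0.05. Every lamina propria pool lay below every marrow pool, with pool 3 at 3.66. What this probe set reads is not analysed here.

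Probe sets with an ID below the lowest ID in the gene table were lower in the lamina propria more often than named ones. Of 6617 such probe sets, 315 (4.76%, exact 95% interval 4.26 to 5.3) were at least 2 lower with no overlap, against 222 of 21789 named ones (1.02%, exact 95% interval 0.89 to 1.16), while 17 and 14 were at least 2 higher.

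Of the tests on this pattern, those of wide scatter and of the narrower value range were chosen after the result was seen, and that of unspliced or genomic sequence before. A candidate explanation is that these probe sets scatter widely in every array while pools 1 and 2 are shifted. In pool 3, 250 of them lay at least 2 below the bone marrow mean and 289 at least 2 above, so 46.4% of those were below (exact 95% interval 42.1 to 50.7), and the bone marrow arrays, each against the other 2, had 218, 114 and 311 below. The narrower range of pools 1 and 2 as the source stays open: the share in pool 3, 3.78% against 0.115% of named probe sets, was meant to argue against it, but the marrow arrays scatter as much, so that share decides nothing. More unspliced or genomic sequence in the marrow samples also stays open. MicroRNA genes, often inside introns, were at least 1 lower with no overlap 0.352 times as often as genes of the same level (exact 95% interval 0.0427 to 1.27), a bound under the 1.5 set beforehand to argue against it, yet only 29.6% of the 291 microRNA genes lie above the median level, and genes near the floor cannot exclude it. A tissue difference is untested for these probe sets.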

How the results depend on the processing

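Leaving out pools 1 and 2 together, and a threshold of 0.01 for lists, were chosen after seeing the data. The labels do not say whether the pool numbers pair the samples. Deviations of same-numbered pools correlated across genes at 0.131, 0.051 and 0.226, not all high enough to treat them as pairs, and not every pool correlated best with its own number, which does not exclude pairing. With the replicate block limma called 2 genes higher and 14 lower, with an intensity trend and robust variances 1 and 39, and with array weights 3368 and 2218. Leaving out 1 array gave 0 to 4806 higher and 0 to 2416 lower, the upper ends without lamina propria pool 3, where 5345 of 7222 calls were shared with array weights. The other settings gave 0. Lists past the threshold, 3 higher and 4 lower, became 0 and 0 with an estimated correlation and with fry. There the V(D)J (median -1.05), pro-B and pre-B (-0.22), pan-B (-0.31), cell cycle (-0.33), stress (0.78), T cell (0.43) and epithelium (0.41) calls were lost. At an adjusted p under 0.01, 1 list was higher and 3 lower: pan-B (-0.31, adjusted p = 0.0109), T cell (0.43, 0.0178) and epithelium (0.41, 0.0109) were lost to the threshold itself. Matched random lists left 2 lower: pro-B and pre-B (-0.22), cell cycle (-0.33), T cell (0.43) and epithelium (0.41) were lost, NF-kB targets (0.47) and microbial sensing (-0.082) now passed, ribosomal protein genes (0.11) turned and passed as higher (adjusted p = 0.0162), and pan-B (-0.31) turned without passing (adjusted p = 0.99). With genes above the median level only, 1 list was lower: pro-B and pre-B (-0.23), pan-B (-0.36), cell cycle (-0.38), T cell (0.27) and epithelium (0.44) were lost, and NF-kB targets (0.49) passed. After quantile normalization once more pan-B (-0.14) was lost and NF-kB targets (0.64) passed. With array weights 0 lists were higher, and stress (0.73), T cell (0.57) and epithelium (0.45) were lost. Leaving out 1 array gave 0 to 4 lists higher, 0 without lamina propria pool 3, and 3 to 4 lower. Medians then ran from -1.26 to -0.66 for V(D)J, -0.60 to -0.23 for pro-B and pre-B, -0.45 to -0.13 for pan-B, -0.50 to -0.10 for cell cycle, 0.62 to 0.92 for stress, 0.37 to 0.56 for T cell, 0.29 to 0.45 for epithelium, 0.34 to 0.60 for NF-kB targets and -0.12 to 0.26 for ribosomal protein genes. Pan-B was lost without lamina propria pool 2 or marrow pool 1, stress, T cell and epithelium without lamina propria pool 3, and cell cycle without marrow pool 3, where ribosomal protein genes passed as lower, while NF-kB targets passed without lamina propria pool 2. Without pools 1 and 2, 8 lists were higher and 2 lower: pro-B and pre-B (-0.15) and cell cycle (-0.093) were lost, pan-B (0.11) reversed, and MHC class II (0.79), plasma cell (0.17), NF-kB (0.70), glycolysis (0.37), macrophage (0.27) and, lower, granulocyte (-0.44) lists passed. The V(D)J list kept its direction in every setting and its call in all but the estimated correlation and fry. The median difference over genes, 0.22, was 0.13 with arrays shifted to the same median and 0.12 after quantile normalization. Of 62 genes named by the rule, 16 passed with array weights, 18 without lamina propria pool 3, and 1, Rag2, with the block and with the trend. Of 33 others, Xrcc4, Atf3, Hspa1a and Mir103-2 passed with the block (adjusted p = 0.0476 each), Xrcc4, Atf3, Mir103-2, Atxn1 and Tlr4 with the trend, and 16 with array weights and 17 without pool 3. Apart from fewer arrays or genes, the cause was not tested.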

Other observations

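Of the tests below, those of a mislabelled pool and of enterocyte RNA, and the choice of the genes and families named in the next 2 paragraphs, came after the values were seen.

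In pool 3, whose value range was that of the bone marrow arrays, 4 of the 8 MHC class II presentation genes lay at least 1 above the marrow. H2-Aa lay 2.37 above the bone marrow mean, Cd74, the invariant chain that guides MHC class II molecules, 2.20, H2-Ab1 2.12 and H2-Eb1 1.21, each above all 3 marrow pools. Ciita lay 0.37 above, and H2-DMa (0.17), H2-Ob (0.11) and H2-Oa (-0.41) lay inside the marrow range. Of the 4, only Cd74 was also higher in pools 1 and 2 than in every marrow pool, with a difference over the 3 pools of 1.504 (95% interval 0.72 to 2.29, limma adjusted p = 0.281). Markers of macrophages, monocytes and dendritic cells, some of which express MHC class II, had a median of 0.271 in pool 3 (camera adjusted p = 0.00651 without pools 1 and 2). Of 16 members 7 lay there above all 3 marrow pools, 7 inside their range and 2 below. Csf1r lay 0.95, C1qc 0.84, Fcer1g 0.83 and C1qb 0.72 above the marrow mean and Cd68 0.84 below. Lyz2 lay 1.34 above, but was lower by 1.315 in pools 1 and 2 (adjusted p = 0.0208 without pool 3). Which cells the MHC class II and Cd74 values come from was not tested. Jchain, which links IgA and IgM into polymers, was 1.41 higher (95% interval 0.71 to 2.11, adjusted p = 0.268) with no overlap, at 4.64 in pool 3 against a marrow mean of 3.01. The fetal-type RNA-binding protein gene Igf2bp3 differed by -1.19 (95% interval -1.62 to -0.75, adjusted p = 0.172) and Tlr4, the receptor for bacterial lipopolysaccharide, by -1.48 (95% interval -1.99 to -0.97, adjusted p = 0.155, and 0.0362 with an intensity trend and robust variances), both lower in all 3 lamina propria pools.

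Genes named Zfp with a number, mostly zinc finger proteins, were often lower. Of 347 such genes, 50 (14.4%) were at least 1 lower with no overlap, where genes of the same marrow level would give 15.2. The family was picked from the same 6 arrays, so this count describes it and tests nothing. In pool 3 alone their median difference was -0.17 and 68.6% lay below the marrow mean. Of the 60 genes with the widest gap between the tissues, 55 were lower in the lamina propria, led by Mir103-2 at -3.05 and Atxn1 at -4.54, and 8 of those 55 were Zfp genes. Of the 5 higher, 1 was Zfp622, at 1.75 with no overlap. Over all genes with no overlap, 2960 were higher and 1450 lower, but 67 and 872 where the difference was at least 1.

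Lamina propria pools 1 and 2 lay apart from pool 3 and from the marrow. A wrong label of pool 3 stays open. Of 27 genes at least 1 above every marrow value in pools 1 and 2, with a mean over those pools above 7, pool 3 lay above every marrow value in 21, 77.8% (exact 95% interval 57.7 to 91.4), a lower bound meant to argue against it. Choosing genes against the marrow arrays lifts that share by itself: with 1 marrow pool held out and genes chosen against the other 2, the held-out pool lay above both in 45.7%, 70.5% and 37.1%, and pool 3 in 80%, 77.3% and 77.1%. Some other values of pool 3 lay on the lamina propria side. Of the 12 V(D)J genes, 8 lay below all 3 marrow pools, 4 inside their range and 0 above. Probe set 10338581 lay at 3.66, against 3.82 and 4.28 in pools 1 and 2 and a marrow mean of 9.41 ± 0.33 (SD, n = 3). These values come from 1 array, and the probe set was picked after its values were seen, so they do not settle the label. Random loss of transcripts in amplification from little RNA may account for part and also stays open: among 1689 genes with a marrow mean of at least 8, 487 and 561 lay at least 2 lower in pools 1 and 2, 263 in both, 1.51 times the 174.6 of independent losses (bootstrap 95% interval 1.4 to 1.61), between the bounds set beforehand. Pool 3 had 5 such genes. A difference between the sorted cells of these pools is untested.

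T cell markers, intestinal epithelium markers, and immediate early and stress genes passed as higher by camera at its preset correlation. None of the 3 lists passed with an estimated correlation (adjusted p = 0.665, 0.605 and 0.605 with an estimated correlation) or without lamina propria pool 3 (adjusted p = 0.113 each). Without that pool their medians were 0.56, 0.44 and 0.68. For T cell and epithelium markers, the narrower value range of pools 1 and 2, which lifts dim genes, stays open as the whole cause. The list medians stood at percentiles 98.12, 97.92 and 100 of random lists matched on level, a test meant to argue against it. Such lists draw genes independently, while the members' estimated correlations were 0.257, 0.154 and 0.349, so these percentiles cannot decide. For T cell and epithelium markers the random lists themselves had medians of 0.267 and 0.3. For stress genes the random lists had a median of -0.115, so at their levels the narrower range brings a fall. The stress list had a median difference of 0.78, and stood at 0.59, 0.97 and 0.66 in pools 1, 2 and 3. These values argue against the narrower range as the whole cause for the stress list. In pool 3 alone, with no narrower range, the list medians were 0.27, 0.17 and 0.66, at percentiles 100, 99.92 and 100, but this rests on 1 array. After adjustment over the lists, the first and second did not pass among matched lists (adjusted p = 0.113 each). RNA of gut cells carried into the sort may contribute and cannot be excluded: the median of 6 enterocyte transcripts (Fabp1, Fabp2, Apoa1, Apoa4, Alpi and Vil1) in pool 3 was 0.046 above the marrow mean, against 0.299 for the other 16 epithelial markers, but 1 of the 6 lay above the median level of all genes, so the levels are too low to decide. Whether the sort for the reporter removed such cells and their RNA was not tested. Effects of tissue dissociation on stress genes are untested, as is a tissue difference in all 3 lists.

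Chance was tested with the 10 splits of the 6 arrays into 3 and 3, too few for a share under 0.05. At an adjusted p under 0.05 the real split gave 0 genes and the highest other 0, so 10 of 10 gave as many. At an unadjusted p under 0.05 the real split gave 2728 and the highest other 2694, so 1 of 10 gave as many. That other split kept lamina propria pools 1 and 2 together with marrow pool 1, which points to the structure of these pools. For lists the real split gave 7 and the highest other 9, so 4 of 10 gave as many.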
